A study of Homo sapiens with 6 samples.

How the data were processed

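RNA was measured in 6 libraries of H9, an established human embryonic stem cell line, in 3 groups of 2. The groups were primed cells in mTeSR medium, cells in RSeT, a commercial medium used to hold cells in a naive-like state, and RSeT cells that also received 10 nM DZNep and 5 nM TSA and were collected after 48 hours (RSeT+DT). DZNep inhibits S-adenosylhomocysteine hydrolase and lowers EZH2 and its histone mark H3K27me3, and TSA (trichostatin A) inhibits histone deacetylases. Per the labels' protocols, RNA was extracted with a miRNeasy kit and libraries were made with a stranded total RNA kit, so RNA without a poly(A) tail is included.

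Both deposited tables list repeats by name. The first holds raw counts per repeat, as deposited by the authors, with 15600 entries, of which 14233 carry the name of a simple or low-complexity repeat. The deposited CPM table holds 7383 of these entries. Its values equal counts per summed counts of the listed entries, scaled to CPM, within 0.00442 CPM. Entries listed there have a total of at least 10 counts over the 6 libraries, and the largest total of an unlisted entry is 9. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.8a, featureCounts and Subread 2.14.2 were used with the GRCh38/hg38 build. The roles of these tools, the repeat annotation, the treatment of reads that map to many places and the strand setting are not given in the sources used here. Each count is a sum over all genomic copies of a repeat, so no coordinates belong to a value, and closely related subfamilies, such as neighbouring LINE1 or LTR subfamilies, can share reads. Repeats that lie in introns or untranslated regions also count reads of the host transcript. Gene-level values were not analysed here, so the gene lists drawn up for the design were not used.

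Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, all 6 libraries in one fit with group as the only term, and Benjamini-Hochberg adjustment over all features at a threshold of 0.05. Repeats were kept by filterByExpr with its settings of at least 10 counts and a total of 15, which left 4665 features: 3433 simple repeats and 1232 others, 1136 of them interspersed repeats. Log2 fold changes are those of the fit, and standard errors (SE) were derived from the fold change and the F statistic. Levels are the deposited CPM as mean ± SD. The common biological coefficient of variation was 5.49%, with 3 residual degrees of freedom. With 2 against 2 libraries an exact two-sided permutation test cannot go below p = 0.333, so all p-values rest on the model. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 17.0 in RSeT+DT, 6.02 in RSeT and 30.5 in primed cells.

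Repeats were grouped by name into 18 lists, as the tables used here have no class column. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The latter test has only the 3 residual degrees of freedom of the fit and so has little power. A higher p there need not mean that members are correlated. For the 8-cell LTRs in RSeT against primed cells, camera's adjusted p went from 0.00894 to 0.205 at an estimated correlation of -0.16. Camera sets the members against all other tested repeats, so its direction can differ from the sign of the list median. The lists, their tests, the rule for named repeats and the alternatives were fixed before the data were examined, with these exceptions. The name patterns of the DNA transposon list were corrected after the repeat names were seen, because the first version also took LTR subfamilies such as MER11B and MER21A, and the thinning of RSeT replicate 1 to the total of RSeT replicate 2 was added after the library totals were seen. The named repeats of a comparison are, among features other than simple repeats that pass the test, have a mean count of at least 50 and do not overlap between the groups, the 10 largest rises and the 10 largest falls, plus anchor repeats named in advance. Examples of a list were picked by hand among the members that pass, mostly by the smallest adjusted p.

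Alternatives were RLE size factors, library totals without TMM, totals implied by the deposited CPM, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0, limma on log2 of the deposited CPM plus 1 or 0.1, the replicate number as a block, only the groups compared, a minimum change of 2-fold, and each library left out in turn. A further alternative, called interspersed scaling here, left small RNA, ribosomal RNA and simple repeats out before normalization. The test was checked on simulated counts for 4665 features, 50 of them changed at each of 4 sizes. For RSeT+DT against RSeT it recovered 20% of 1.2-fold, 32% of 1.5-fold, 68% of 2-fold and 98% of 4-fold changes, with 7 false calls among 4465 unchanged features. For RSeT against primed cells it recovered 78% of 2-fold changes and made 8 false calls, and for RSeT+DT against primed cells 76% and 4. The simulation took its spread from the same fit and changed only 200 features, with as many rises as falls. It therefore does not measure false calls where many features change, or change mostly in 1 direction, as in these data. Plots were drawn with matplotlib 3.10.9.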

Results

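Total RNA from primed, RSeT and RSeT+DT H9 cells was compared for the RNA of repeats, among them LINE1 elements, endogenous retroviruses, satellites and ribosomal RNA. The title of the series places the data in a study of LINE1, the Polycomb complex PRC2, nucleolar organisation and the repression of an 8-cell-like (8C) state. Counts assigned to repeats summed to 16838730 and 13628911 in the primed libraries, 38312112 and 17191110 in the RSeT libraries, and 13064045 and 11520770 in the RSeT+DT libraries. RSeT replicate 1 was thus the deepest library. Log2 CPM of replicates correlated across features with Pearson's r of 0.992, 0.994 and 0.987 in primed, RSeT and RSeT+DT cells, where features are not independent replicates.

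A few classes held most counts and differed between groups, as mean ± SD of the percentage of repeat counts (n = 2 each). Small RNA took 25.4 ± 1.5% in primed, 17.4 ± 0.61% in RSeT and 24.4 ± 1.8% in RSeT+DT cells. Most of this was 7SLRNA, the RNA of the signal recognition particle, at 21.3 ± 1.1%, 14.4 ± 0.44% and 20.2 ± 1.5%. The share of the class thus follows this RNA and not the direction of most members. HERVH and its LTR7 promoters, a primate retrovirus family active in pluripotent cells, took 2.91 ± 0.21%, 8.51 ± 0.17% and 13.3 ± 0.3%. This list, HERVH_LTR7, was built by name and also holds HERVH48-int, which is listed apart from HERVH-int. Its member LTR7B is also counted among the 8-cell LTRs. Satellites took 0.20 ± 0.0096%, 3.39 ± 0.018% and 0.921 ± 0.041%. Alu elements took 19.7 ± 0.47%, 18.0 ± 0.32% and 14.7 ± 0.5%, and simple repeats 11.8 ± 0.29%, 9.86 ± 0.096% and 11.4 ± 0.086%. Ribosomal RNA took 0.654 ± 0.68%, 0.655 ± 0.092% and 1.59 ± 0.71%, with 1.14% and 0.172% in the primed replicates 1 and 2. The direction of small changes depended on the scaling. Interspersed scaling shifted log2 fold changes by 0.22 for RSeT+DT against RSeT, by -0.16 for RSeT against primed cells and by 0.06 for RSeT+DT against primed cells, in the median. Directions that differ are given under both scalings.

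**Figure D1:**
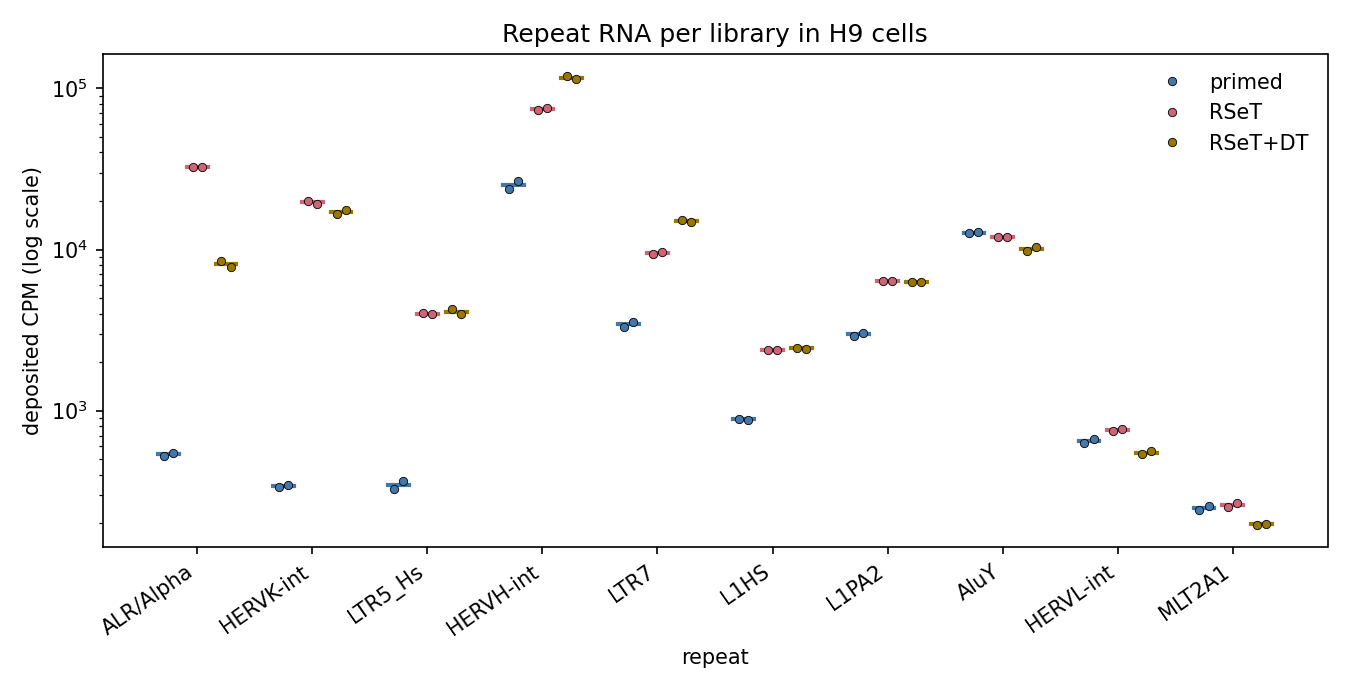
Deposited CPM (log scale) of 10 repeats in each library. Points are libraries, bars are group means, and colours mark primed, RSeT and RSeT+DT cells. ALR/Alpha lay at 536 CPM in primed, 32460 in RSeT and 8137 in RSeT+DT cells, while HERVH-int lay at 25170, 74530 and 116700.

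RSeT against primed cells asks which repeats differ between the naive-like and the primed culture. The largest rises were in ALR/Alpha, the alpha satellite of centromeres, from 536.2 ± 17.8 to 32460 ± 141 CPM (n = 2 each; log2 fold change 6.05, SE 0.041), in the satellite ACRO1 (6.05, SE 0.17) and in HERVK-int, the internal part of the youngest human retrovirus family, from 340.1 ± 6.11 to 19650 ± 594 CPM (5.98, SE 0.034). The HERVK promoter LTR5_Hs rose by 3.66 and LTR5 by 2.11 on the log2 scale. HERVH48-int (3.23), MER48 (2.83), HERVH-int (1.70), LTR7 (1.60) and LTR7Y (1.14) also rose, as did L1P4d (1.99), L1P4e (1.92) and MER136 (1.81). Each of these rises passed under RLE, library totals and interspersed scaling as well. The largest falls were smaller: hAT-16_Crp (-1.70), LTR47B (-1.04), HSAT4 (-1.04), MLT1E3-int (-0.99), LTR18C (-0.90), D20S16 (-0.75), UCON80 (-0.71), HERVFH19-int (-0.69), LTR12E (-0.68) and HERVP71A-int (-0.68). The fall of UCON80 did not pass without RSeT replicate 1 (-0.36) or in DESeq2 (-0.64).

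LINE1, the family of retrotransposons still mobile in humans, was higher in RSeT than in primed cells across its age range with TMM, and in its young and older primate parts under both scalings. All 9 young subfamilies rose, led by L1HS from 882.5 ± 4.94 to 2385 ± 2.24 CPM (1.57, SE 0.044), L1PA2 (1.24), L1PA8A (0.98) and L1PA3 (0.74), and all 9 also rose under interspersed scaling. Of 29 subfamilies in the list called older primate here 29 rose, among them L1PB2 (1.43) and L1PBa1 (1.13), and 27 did so under interspersed scaling. This list also holds the L1MA subfamilies, which carry the mammalian-wide L1M prefix, so not all its members are specific to primates. Of 55 mammalian-wide subfamilies 43 rose and none fell, but under interspersed scaling 18 rose and 10 fell. The list tests of these groups passed with the preset correlation and not with an estimated one, with adjusted p = 0.121 with an estimated correlation for the young, 0.208 for the older primate and 0.394 for the mammalian list.

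Among the retroviral lists, 3 of 5 members of HERVK_LTR5 and 5 of 7 of HERVH_LTR7 rose and none fell, both with adjusted p = 0.121 with an estimated correlation. Interspersed scaling gave 3 rises and 1 fall, and 4 rises and 1 fall. Of the 6 LTRs and internal parts tied to the 8-cell stage, 5 rose and none fell, among them MLT2A2 (0.46), ERVL-int (0.43), HERVL-int (0.36) and MLT2A1 (0.19, but 0.026 and not passing under interspersed scaling), against 3 rises and 1 fall under interspersed scaling (adjusted p = 0.205 with an estimated correlation). LTR7B rose by 0.09 with TMM, stood at -0.07, not passing, under interspersed scaling, and did not pass without RSeT replicate 1 (0.06), primed replicate 1 (0.09) or primed replicate 2 (0.09). LTR14B had a log2 fold change of -0.010 that did not pass, against -0.17 that passed under interspersed scaling. In the LTR12 and HERV9 list 6 of 10 rose and 3 fell, with LTR12C at 0.56, HERV9NC-int at 1.01 and LTR12D at 0.97 (adjusted p = 0.213 with an estimated correlation). LTRs used in trophoblast, a check for another cell type, had 9 of 14 members higher and 2 lower, led by LTR17 (1.56) and MER50-int (0.87), with 8 and 4 under interspersed scaling (adjusted p = 0.121 with an estimated correlation).

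In SVA 4 of 6 rose and none fell, against 2 and 2 under interspersed scaling, with SVA_F at 0.41 under TMM and SVA_D at 0.12, which turned to -0.039, not passing. In Alu 17 of 47 rose and none fell, against 9 and 25, with AluYb8 (0.65) and AluYd8 (1.05) among the rises and AluY at 0.04, not passing, against -0.12 with a call. THE1 and MST elements had 17 of 24 higher and none lower, against 9 and 3. THE1B rose by 0.14 under TMM and stood at -0.025, not passing, under interspersed scaling. Older MLT elements had 28 of 66 higher and 3 lower, against 9 and 24, DNA transposons 71 of 139 higher and 9 lower, against 25 and 42, and MIR and L2 none of 12 higher and 2 lower, against 0 and 12. Satellites had 9 of 18 higher and 5 lower, against 8 and 7. Small RNA had 43 of 75 higher and 11 lower, among them tRNA-Ala-GCY (1.43) and BC200 (0.92), while 7SK, which controls transcription elongation, fell by 0.41. None of the 3 ribosomal RNA features passed in edgeR (0 at an unadjusted p under 0.05, 0 in DESeq2). LSU-rRNA_Hsa stood at 0.16, but at -0.58 without primed replicate 2 and at 1.83 without primed replicate 1. SSU-rRNA_Hsa stood at 0.04, but at -0.83 and 2.69 without these libraries, and 5S at 0.05. The primed replicates differ by 2.42 (LSU-rRNA_Hsa) and 3.52 (SSU-rRNA_Hsa) on the log2 scale, and with 1 primed library left the spread comes from the other groups, so calls of those fits are not used. With an estimated correlation, adjusted p was 0.36 for SVA, Alu, older MLT elements and small RNA, 0.344 for THE1 and MST elements and DNA transposons, 0.283 for satellites and 0.92 for MIR and L2. SVA and MIR and L2 did not pass with the preset correlation either, and neither did ribosomal RNA.

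Over all 4665 features, 1064 rose and 1110 fell in RSeT against primed cells. Of 1136 interspersed repeats 577 rose and 91 fell, against 338 and 298 under interspersed scaling, which sets their median near 0. Of 3433 simple repeats 435 rose and 1003 fell, the one list that passed with an estimated correlation (adjusted p = 0.0161). With library totals and no TMM, 683 features rose and 1533 fell, and 376 rose and 210 fell among features other than simple repeats, against 629 and 107 with TMM. By list, library totals gave 4 higher and 1 lower for HERVH_LTR7, 8 and 3 for THE1 and MST elements, 10 and 9 for older MLT elements, 2 and 1 for SVA, 9 and 11 for Alu, 8 and 7 for satellites, 25 and 24 for DNA transposons and 307 and 1323 for simple repeats. Adjusted over the list alone, the calls were 4 higher for HERVK_LTR5, 7 higher and 3 lower for LTR12 and HERV9, 29 and 3 for older MLT elements, 4 and 1 for SVA, 44 higher for mammalian LINE1, 16 higher for Alu, 44 and 11 for small RNA and 421 and 978 for simple repeats, and equal in number in the other lists.

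**Figure D2:**
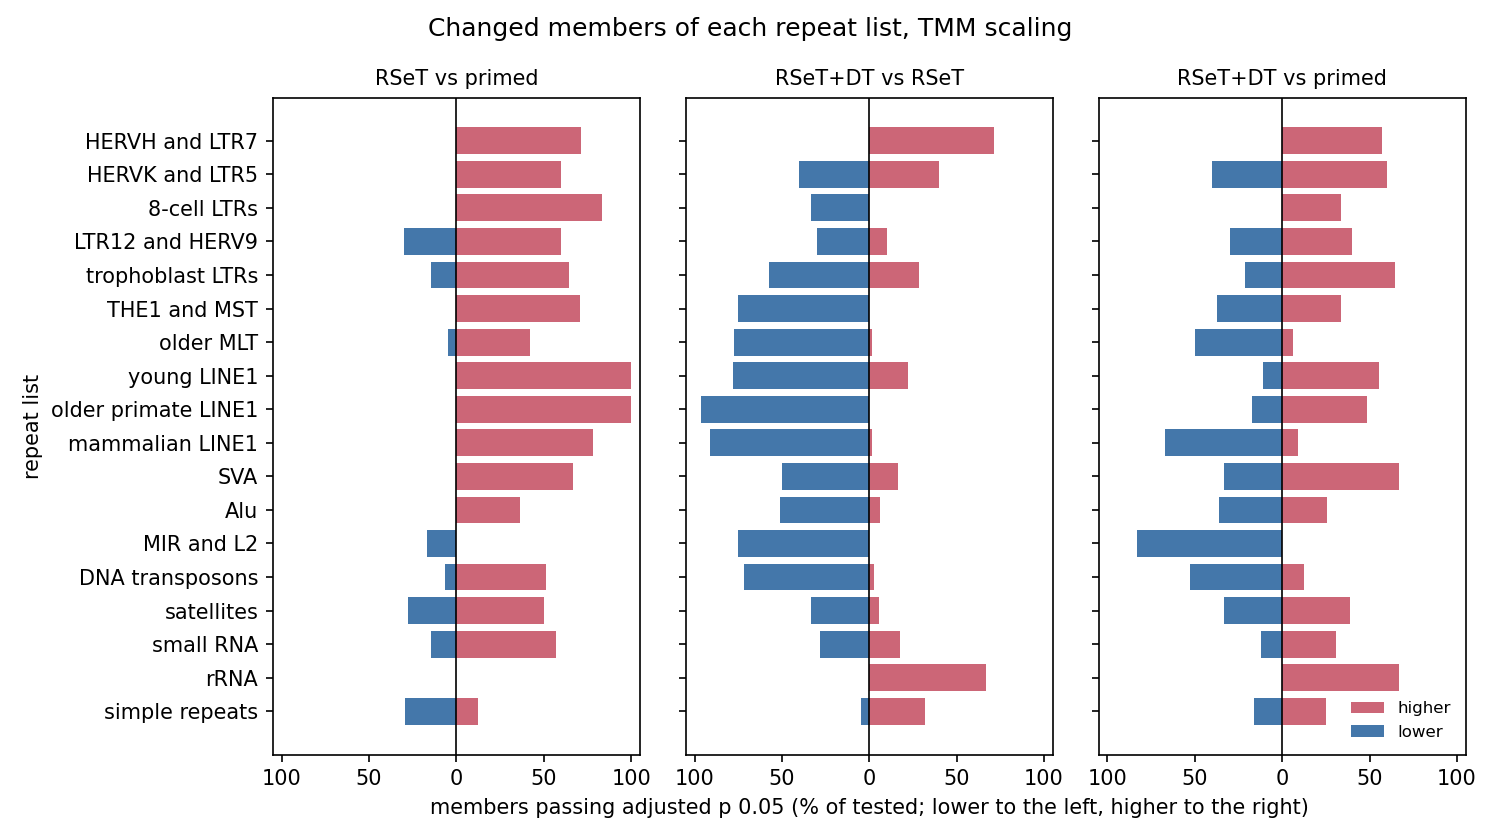
Members of each repeat list that passed adjusted p 0.05 with TMM scaling, as a percentage of tested members, higher to the right and lower to the left. All 29 subfamilies of the list called older primate LINE1, which also holds L1MA subfamilies, rose in RSeT against primed cells and 28 fell in RSeT+DT against RSeT. Under interspersed scaling the calls for Alu, SVA and the 8-cell LTRs in RSeT+DT against RSeT went mainly the other way.

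RSeT+DT against RSeT asks what 48 hours with DZNep and TSA changed. Of 7 HERVH_LTR7 members 5 rose and none fell, with LTR7A (0.20) and LTR7B (-0.044) not passing. In camera the adjusted p for the list was 0.00342 with the preset correlation and 0.254 with an estimated correlation. HERVH-int went from 74530 ± 1540 to 116700 ± 2670 CPM (n = 2 each; log2 fold change 0.80, SE 0.025), LTR7 from 9538 ± 172 to 15000 ± 328 CPM (0.81, SE 0.032), HERVH48-int rose by 0.75, MER48 by 0.68 and LTR7Y by 0.38. Under interspersed scaling 6 of the 7 rose, with HERVH-int at 1.02 and LTR7 at 1.03. ALR/Alpha fell from 32460 ± 141 to 8137 ± 415 CPM (-1.84, SE 0.034; adjusted p = 1.79e-23, edgeR's quasi-likelihood test) and ACRO1 fell from 66.42 ± 3.89 to 27.79 ± 6.61 CPM (-1.11, SE 0.095). Both also fell under interspersed scaling, by 1.62 and 0.89 on the log2 scale. The other largest falls were tRNA-Ala-GCA (-1.59), UCON53 (-1.29), L1P3b (-1.21), PRIMAX-int (-1.14), tRNA-Ala-GCY (-1.09), Eulor6B (-0.98), UCON33 (-0.93) and HERV4_I-int (-0.92). Eulor6B did not pass without RSeT+DT replicate 1 (-0.82).

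7SK rose from 15500 ± 180 to 22650 ± 495 CPM (0.70, SE 0.028), 7SLRNA, the RNA of the signal recognition particle, by 0.64, tRNA-Leu-TTA(m) by 0.72 and UCON27 by 0.74. U3, a small nucleolar RNA that acts in the processing of ribosomal RNA, rose by 0.87 and did not pass in DESeq2. LSU-rRNA_Hsa was at 6559 and 11210 CPM in the RSeT+DT libraries against 4005 and 3637 in the RSeT libraries (1.36, SE 0.35), and SSU-rRNA_Hsa at 4225 and 9654 against 3145 and 2211 (1.52, SE 0.50). Both passed in edgeR and not in DESeq2. LSU-rRNA_Hsa did not pass without RSeT replicate 2 (1.29), nor did SSU-rRNA_Hsa without RSeT+DT replicate 2 (0.85), RSeT replicate 1 (1.81) or RSeT replicate 2 (1.28). 5S stood at -0.08, not passing, and at -0.23 with a call with library totals. Small RNA as a list had 13 of 75 members higher and 21 lower, and its test passed as lower (adjusted p = 0.566 with an estimated correlation), and ribosomal RNA 2 of 3 higher.

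The 8-cell LTRs did not rise as a group. With TMM, 2 of 6 fell, HERVL-int from 761.2 ± 19.2 to 546.9 ± 17.1 CPM (-0.32, SE 0.044) and MLT2A1 from 259.2 ± 10.6 to 197.1 ± 1.79 CPM (-0.24, SE 0.038), and none rose. MLT2A2 (-0.0058), LTR7B (-0.044), ERVL-int (-0.030) and LTR14B (0.014) did not pass. With library totals MLT2A2 (-0.16) and LTR7B (-0.20) were lower with a call, whereas under interspersed scaling 4 of the 6 rose, among them MLT2A2 (0.21), LTR7B (0.17) and LTR14B (0.23), HERVL-int still fell (-0.10), and MLT2A1 stood at -0.018, not passing. The list test passed with neither of TMM and interspersed scaling, and as lower with library totals (0 higher and 5 lower). With TMM and an estimated correlation, its adjusted p in camera was 0.345. Library totals were not tested with an estimated correlation. HERVK-int stood at -0.056, not passing, with TMM, at -0.21 with a call with library totals and at 0.16 with a call under interspersed scaling, and LTR5_Hs rose by 0.20 with TMM and stood at 0.044, not passing, with library totals. In the HERVK list 2 of 5 rose and 2 fell, the falls being LTR5A (-0.45) and LTR5B (-0.13), against 3 and 1 under interspersed scaling. LTR12C stood at 0.039, not passing, and rose by 0.26 under interspersed scaling, and LTR12 and HERV9 had 1 of 10 higher and 3 lower, against 6 and 0.

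Most LINE1 subfamilies fell in RSeT+DT with TMM, while L1HS, L1PA2 and L1MDb (0.17) rose. L1HS rose by 0.18 (SE 0.043) and L1PA2 by 0.12 (SE 0.033), but with library totals L1HS stood at 0.027 and L1PA2 at -0.029, neither passing. The other 7 young subfamilies fell with TMM, among them L1PA4 (-0.43), L1PA7 (-0.41) and L1PA5 (-0.39). Under interspersed scaling 3 of all 9 young subfamilies rose and 5 fell. The rises were L1HS (0.40), L1PA2 (0.34) and L1PA3 (-0.11 with TMM, 0.11 with interspersed scaling). Of 29 subfamilies in the older primate list 28 fell and none rose, among them L1MA6 (-0.55) and L1PA11 (-0.54), with 23 lower and 1 higher under interspersed scaling. Of 55 mammalian-wide subfamilies 50 fell and 1 rose, with 44 and 4 under interspersed scaling. The adjusted p with an estimated correlation was 0.343 for the young, 0.254 for the older primate and 0.343 for the mammalian list.

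THE1 and MST elements had 18 of 24 lower and none higher with TMM, against 4 lower and 6 higher under interspersed scaling, where THE1B (-0.28 with TMM) stood at -0.057, not passing. Older MLT elements had 51 of 66 lower and 1 higher, against 6 and 9. DNA transposons had 100 of 139 lower and 4 higher, against 47 and 20, and MIR and L2 9 of 12 lower, against 0 lower and 2 higher. Alu had 24 of 47 lower and 3 higher, against 0 and 25, with AluY at -0.10 with TMM and 0.12 under interspersed scaling. SVA had 3 of 6 lower and 1 higher, against 0 and 5, with SVA_E at 0.28 and SVA_D (0.04) and SVA_F (-0.030) not passing with TMM. SVA_F was at -0.18 with library totals and at 0.19 under interspersed scaling, both with a call. Satellites had 6 of 18 lower and 1 higher, against 5 and 7, with SATR2 (-0.84) and BSR/Beta (-0.40) among the falls under TMM. The trophoblast LTRs had 4 of 14 higher and 8 lower, against 6 and 0, with LTR17 at 0.46 and MER21A at -0.28 under TMM. The list tests of Alu, SVA and trophoblast LTRs passed as higher under interspersed scaling, while with TMM Alu passed as lower and the other 2 did not pass. With TMM and an estimated correlation, adjusted p in camera was 0.254 for older MLT elements, satellites and DNA transposons, 0.343 for THE1 and MST elements and 0.471 for Alu and for MIR and L2. It was 0.667 for SVA and 0.386 for trophoblast LTRs. Interspersed scaling was not tested with an estimated correlation.

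Over all features, 1168 rose and 810 fell in RSeT+DT against RSeT. Of 1136 interspersed repeats 63 rose and 621 fell, against 254 and 234 under interspersed scaling, which sets their median near 0. Of 3433 simple repeats 1089 rose and 162 fell (adjusted p = 0.0104 in camera with an estimated correlation). With library totals, 789 features rose and 1156 fell, and among features other than simple repeats 38 rose and 872 fell, against 79 and 648 with TMM. By list, library totals gave 4 higher and 1 lower for HERVH_LTR7, 0 and 3 for HERVK_LTR5, 0 and 6 for LTR12 and HERV9, 0 and 4 for SVA, 0 and 7 for young LINE1, 0 and 35 for Alu, 10 and 32 for small RNA, 2 and 1 for ribosomal RNA, 2 and 10 for trophoblast LTRs, which passed as lower, and 751 and 284 for simple repeats. At least a 2-fold change was seen in 2 rises and 12 falls among features other than simple repeats. Adjusted over the list alone, the calls were 1 higher and 54 lower for older MLT elements, 1 and 52 for mammalian LINE1, 4 and 24 for Alu, 4 and 107 for DNA transposons, 4 and 9 for trophoblast LTRs and 1051 and 149 for simple repeats, and equal in number in the other lists.

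RSeT+DT against primed cells compares both ends of the series. HERVK-int (5.93, SE 0.034), ACRO1 (4.94), ALR/Alpha (4.21), HERVH48-int (3.99), LTR5_Hs (3.86), MER48 (3.51), HERVH-int (2.50), LTR5 (2.43), LTR7 (2.41) and LTR17 (2.03) had the largest rises, and LTR7Y rose by 1.53. HERVH-int lay at 25170 ± 1900 CPM in primed and 116700 ± 2670 CPM in RSeT+DT cells (n = 2 each). L1HS (1.75), L1PA2 (1.36) and L1PA3 (0.63) rose under each scaling, as did LTR12C (0.60) and MLT2A2 (0.45). The largest falls were hAT-16_Crp (-1.69), MLT1E3-int (-1.60), HSAT4 (-1.33), HERVFH21-int (-1.09), tRNA-Gly-GGY (-1.09), L1P3b (-1.07), tRNA-Ala-GCA (-1.07), HERVP71A-int (-1.02), LTR57-int (-0.96) and UCON23 (-0.93). LSU-rRNA_Hsa (1.53; 6177 and 1203 CPM in primed, 6559 and 11210 in RSeT+DT) and SSU-rRNA_Hsa (1.56; 5134 and 465.3 against 4225 and 9654, which overlap) passed in edgeR and not in DESeq2. SSU-rRNA_Hsa did not pass without RSeT+DT replicate 2 (0.91). With 1 primed library left out, LSU-rRNA_Hsa stood at 0.78 or 3.20 and SSU-rRNA_Hsa at 0.69 or 4.21. MLT2A1 (-0.050), HERVL-int (0.039), LTR7B (0.043), LTR14B (0.0044), 5S (-0.029) and AluY (-0.056) did not pass with TMM, nor did MLT2A1 (0.0082) and AluY (0.0016) with interspersed scaling, where their sign turned. HERVL-int passed at -0.25 with library totals and at 0.098 with interspersed scaling, and MLT2A1 (-0.34), LTR14B (-0.28), AluY (-0.34) and 5S (-0.31) passed with library totals. LTR7B passed at -0.24 with library totals and at 0.10 with interspersed scaling. SVA_D (0.17) and SVA_F (0.38) rose with TMM and THE1B fell (-0.14), while with library totals SVA_D was at -0.12 and SVA_F at 0.09, neither passing.

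By list with TMM, HERVH_LTR7 had 4 of 7 members higher and none lower, HERVK_LTR5 3 of 5 higher and 2 lower (3 and 1 under interspersed scaling), and trophoblast LTRs 9 of 14 higher and 3 lower, each with adjusted p = 0.281 with an estimated correlation. Young LINE1 had 5 of 9 higher and 1 lower, against 7 and 0, but a median of -0.17 with library totals against 0.12 with TMM (0.551 as the adjusted p with an estimated correlation), and older primate LINE1 14 of 29 higher and 5 lower, led by L1PB2 (1.16) and L1PBa1 (0.92), while mammalian LINE1 had 5 of 55 higher and 37 lower (0.66 likewise). Older MLT elements had 4 of 66 higher and 33 lower, against 14 and 25, DNA transposons 17 of 139 higher and 73 lower, and MIR and L2 none of 12 higher and 10 lower, each with adjusted p = 0.659 with an estimated correlation. The lists of 8-cell LTRs (2 of 6 higher, none lower), LTR12 and HERV9 (4 of 10 higher, 3 lower), THE1 and MST elements (8 of 24 higher, 9 lower, against 10 and 7), SVA (4 of 6 higher, 2 lower, against 4 and 1), Alu (12 of 47 higher, 17 lower, against 16 and 13), satellites (7 of 18 higher, 6 lower), small RNA (23 of 75 higher, 9 lower), ribosomal RNA (2 of 3 higher) and simple repeats (864 of 3433 higher, 557 lower) did not pass as lists with TMM, nor did older primate LINE1. With library totals the balance moved towards falls in many lists. It turned or evened with 1 higher and 4 lower for 8-cell LTRs, 4 and 4 for LTR12 and HERV9, 1 and 2 for SVA, 4 and 5 for young LINE1, 4 and 16 for older primate LINE1, 6 and 9 for satellites and 14 and 20 for small RNA. Lists already with more falls went further, with 2 and 16 for THE1 and MST elements, 0 and 50 for mammalian LINE1 and 6 and 31 for Alu. Ribosomal RNA had 2 and 1. Trophoblast LTRs then had 4 higher and 5 lower, a median of -0.019 and no call as a list. Simple repeats had 467 higher and 1063 lower with a median of -0.27, and passed in camera as higher than the other repeats. HERVH_LTR7 had 4 higher and 1 lower. Over all features 1173 rose and 962 fell, against 608 and 1787 with library totals. Among features other than simple repeats 309 rose and 405 fell, against 141 and 724 with library totals and 372 and 341 with interspersed scaling, which also leaves out small RNA. Adjusted over the list alone, the calls were 5 higher and 3 lower for LTR12 and HERV9, 4 and 34 for older MLT elements, 6 and 41 for mammalian LINE1, 18 and 76 for DNA transposons, 9 and 4 for trophoblast LTRs and 854 and 551 for simple repeats, and equal in number in the other lists. HSATII, a pericentromeric satellite named in advance, was listed at 0 in all 6 libraries and was not tested.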

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

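Counts of changed features were 1978, 2174 and 2135 for RSeT+DT against RSeT, RSeT against primed and RSeT+DT against primed cells. No alternative set against them moved them past the bound of the comparison except a 2-fold minimum, which by construction left 198, 625 and 643, and 14, 78 and 76 among features other than simple repeats. The bound was a fixed factor on the number of calls, whichever repeats were called and in whichever direction. Interspersed scaling was not set against these totals. In RSeT+DT against RSeT it called 500 features, of which 340 were also called with TMM in either direction. Leaving out single libraries gave 1539 to 1980, 1581 to 2360 and 1751 to 2082, and a block for the replicate number gave 1148 higher and 801 lower, 1053 and 1104, and 1166 and 961. Residuals of equally numbered replicates correlated at 0.0499, -0.0399 and 0.00153, which gave no sign of pairing by number, and the block changed no call of a named repeat. A culture or preparation shared by equally numbered libraries is not excluded by this. The thinning of RSeT replicate 1 and the first version of the DNA transposon list were chosen after seeing the data. The first moved no count past the bound, and the second left 12, 15 and 8 list calls, as in the main tests. List calls ran from 11 to 13, 15 to 16 and 8 to 11 when single libraries were left out. With an estimated correlation 1, 1 and 0 lists passed in camera (2, 5 and 3 at an unadjusted p under 0.05), and with interspersed scaling 6, 6 and 8, where small RNA, ribosomal RNA and simple repeats cannot be tested. DESeq2 gave no adjusted p for 1357 features of RSeT+DT against RSeT. Of the named results over all alternatives, 1935 counted as the same, 97 became weaker, 56 stronger and 40 reversed. Results that passed in neither fit counted as the same even where their sign turned. The 2-fold minimum by construction gave 20, 16 and 8 of the weaker results in RSeT+DT against RSeT, RSeT against primed and RSeT+DT against primed cells. With ribosomal and small RNA left out of the total, shares in RSeT+DT, RSeT and primed cells were 19.85%, 22.02% and 26.61% for Alu, 17.99%, 10.39% and 3.927% for HERVH_LTR7, 1.245%, 4.134% and 0.2698% for satellites and 15.43%, 12.04% and 16.01% for simple repeats. Interspersed scaling reversed, in RSeT+DT against RSeT, the list medians of SVA (0.1587), Alu (0.08565), trophoblast LTRs (0.08063), MIR and L2 (0.000264) and satellites (0.09743) and the values of MLT2A2 (0.2147), HERVK-int (0.1639), LTR7B (0.1741), L1PA3 (0.1057), SVA_F (0.1891) and AluY (0.1228). In RSeT against primed cells it reversed LTR7B (-0.0731), SVA_D (-0.03863), AluY (-0.1212) and THE1B (-0.02488), the list medians of older MLT elements (-0.05597), Alu (-0.08532), satellites (-0.05064) and DNA transposons (-0.03575), and the camera direction of mammalian LINE1 (median 0.02209). Medians of lists without a call also changed sign: the 8-cell LTRs (-0.037 to 0.18), HERVK_LTR5 (-0.056 to 0.16) and LTR12 and HERV9 (-0.040 to 0.18) in RSeT+DT against RSeT, SVA (0.15 to -0.0082) in RSeT against primed cells, and THE1 and MST elements (-0.026 to 0.033) and Alu (-0.023 to 0.035) in RSeT+DT against primed cells. Library totals reversed the medians of older MLT elements (-0.02503), Alu (-0.05566), satellites (-0.02186) and DNA transposons (-0.008528) in RSeT against primed cells, and of young LINE1 (-0.1671), trophoblast LTRs (-0.01945) and simple repeats (-0.267) in RSeT+DT against primed cells. The alternatives without TMM reversed further values, given here for library totals, totals implied by CPM, and limma with 1 and 0.1 added: L1PA2 in RSeT+DT against RSeT (-0.02906, -0.02881, -0.02881, -0.02881), LTR7B in RSeT against primed (-0.04548, -0.04538, -0.04619, -0.04633), SVA_D there (-0.008917, -0.008823, -0.008927, -0.008933), and in RSeT+DT against primed HERVL-int (-0.2468, -0.2464, -0.246, -0.2464), LTR7B (-0.2429, -0.2425, -0.2419, -0.2427), LTR14B (-0.2815, -0.2812, -0.2774, -0.2822) and SVA_D (-0.1205, -0.1202, -0.1199, -0.12). In RSeT against primed cells LSU-rRNA_Hsa ran from -0.5845 without primed replicate 2 to 1.829 without primed replicate 1, and SSU-rRNA_Hsa from -0.8291 to 2.688. Over the libraries left out in turn, the other results named as reversed ran, in RSeT+DT against RSeT, from -0.0635 to -0.0496 (SVA list), -0.130 to -0.111 (Alu list), -0.140 to -0.128 (trophoblast list), -0.228 to -0.197 (MIR and L2), -0.183 to -0.109 (satellites), -0.0347 to 0.0415 (MLT2A2), -0.0897 to -0.0127 (HERVK-int), -0.0652 to -0.0126 (LTR7B), 0.1095 to 0.160 (L1PA2), -0.122 to -0.0864 (L1PA3), -0.0449 to -0.0066 (SVA_F) and -0.0996 to -0.0743 (AluY). In RSeT against primed cells they ran from 0.0638 to 0.129 (LTR7B), 0.111 to 0.156 (SVA_D), 0.0210 to 0.0650 (AluY), 0.1305 to 0.164 (THE1B), 0.0929 to 0.126 (older MLT elements), 0.184 to 0.211 (mammalian LINE1), 0.0636 to 0.0936 (Alu list), 0.0874 to 0.137 (satellites) and 0.115 to 0.159 (DNA transposons), and in RSeT+DT against primed cells from 0.0416 to 0.0603 (HERVL-int), 0.0504 to 0.0693 (LTR7B), -0.0433 to 0.0858 (LTR14B), 0.168 to 0.203 (SVA_D), 0.125 to 0.139 (young LINE1), -0.0534 to 0.102 (satellites), 0.257 to 0.301 (trophoblast list) and -0.0184 to 0.0176 (simple repeats). A fit with 1 library in a group assumes that this library varies like the other groups. The cause was not tested for any of these changes.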

Other observations

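The simple repeat (GGAAT)n, the motif of satellites II and III that lie beside centromeres, was far higher in RSeT and RSeT+DT than in primed cells. It was picked out after the values were seen. Summed over the 10 rotations of GGAAT on both strands, pentamer repeats reached 32.7 ± 0.649 CPM in primed, 333 ± 26.6 CPM in RSeT and 451 ± 54 CPM in RSeT+DT cells (n = 2 each). Of these, (GGAAT)n made up 0.54 ± 0.245, 265 ± 20.2 and 393 ± 47.3 CPM, with 12 and 5 counts in the primed libraries, 9607 and 4803 in RSeT and 5567 and 4138 in RSeT+DT, a log2 fold change of 9.0 in RSeT against primed cells and of 9.73 in RSeT+DT against primed cells. In RSeT against primed cells (TGGAA)n (5.19), (TCCAT)n (4.83) and (ATGGA)n (4.67) also rose, as did (ATTCC)n (1.06), (AATGG)n (0.84) and (TTCCA)n (0.59) by less, while (GAATG)n, (CCATT)n and (CATTC)n did not pass. In RSeT+DT against RSeT (GGAAT)n rose by 0.73 and (TGGAA)n by 0.38, and the other 8 rotations did not pass, among them (ATGGA)n (-0.58) and (TTCCA)n (-0.36).

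In RSeT+DT against RSeT 1089 of 3433 simple repeats rose and 162 fell with TMM, while 63 of 1136 interspersed repeats rose and 621 fell, and the tests on GC content, low counts and depth were chosen after this was seen but before their own values were known. The gap between their medians was 0.43 (0.21 against -0.22). Low counts do not account for it, since at mean counts of 20 to 200 the gap was 0.481 (0.389 to 0.581), and neither does the depth of RSeT replicate 1, without which it was 0.457 (0.43 to 0.481). Ranges in brackets here and for satellites below come from 2000 bootstrap resamples of repeats. They treat repeats as independent and do not measure the spread between libraries. Median changes rose with the GC content of the motif, from -0.15 at 25% or less to 0.09, 0.30 and 0.50 in the next 3 bins of 25 points. In RSeT against primed cells the same bins stood at 0.13, -0.085, -0.34 and -0.33. In RSeT+DT against primed cells they stood at 0.00249, 0.00805, -0.076 and 0.15, without a steady trend. The gradient was thus clearest in the comparisons that hold the RSeT libraries. In RSeT+DT against RSeT, simple repeats of 25% GC or less stood 0.075 (0.0279 to 0.123) above interspersed repeats, too close to the bounds set to decide. Simple repeats of 25 to 50% GC, at 0.09, stood further above interspersed repeats, at -0.22. A GC-dependent step in library preparation could therefore make up part of the gap. How much cannot be told, as the GC content of interspersed repeats was not used here. Treatment and library preparation are also not separated in these samples.

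For ALR/Alpha and ACRO1 the DNA test was chosen only after its result was seen, and the depth test after the rise was seen but before its own value was known. The other 16 tested satellites had a median log2 fold change of -0.0301 (-0.338 to 0.638) in RSeT against primed cells. Of these, 7 were higher and 5 lower, with a largest value of 2.23. A general rise of satellites was thus not seen. Genomic DNA in the RSeT libraries would add reads by copy number, so it need not raise all satellites alike, and this median cannot exclude it. The (GGAAT)n repeats, grouped with simple repeats, also rose, so the rise is not limited to these 2 satellites. Without RSeT replicate 1 ALR/Alpha stood at 6.05, so depth does not account for it. Whether satellite transcripts rose or DNA was present stays open, as reads over exons and introns, which would show DNA more directly, were not analysed here.

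For ribosomal RNA the test was chosen only after its result was seen. Ribosomal RNA left by a removal step was not measured here, but SSU-rRNA_Hsa differed by up to 3.52 on the log2 scale between replicates (primed), by 1.14 in RSeT+DT and by 0.513 in RSeT, against a change of 1.52 from RSeT to RSeT+DT. The higher ribosomal RNA in RSeT+DT may thus come from variation between libraries, such as uneven removal of ribosomal RNA, and its cause stays open.

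Of 2 further patterns, the LINE1 age test was chosen after its result was seen and the shared-RSeT test before its own value was known, and both stay hypotheses. Across 16 subfamilies from L1HS to L1PA17 the change in RSeT against primed cells had Spearman's rho of -0.5 with age rank (permutation p = 0.051, adjusted p = 0.15), and Pearson's r of -0.581 (permutation p = 0.013, not adjusted). Without L1HS and L1PA2 these were -0.253 and -0.196 (permutation p = 0.38 and 0.5), so the trend may rest on these 2. L1PA8A, among the larger rises of young LINE1, and L1PA15-16 were tested but are not in this series, and the age test was not run with them. Among interspersed repeats 363 rose in RSeT against primed cells and fell in RSeT+DT against RSeT, where 315 would be met if the calls were independent, 10 fell and then rose (5.05), 37 rose in both (32) and 34 fell in both (49.7). These overlaps are with TMM, from 577 rises and 621 falls. Interspersed scaling gave only 338 rises in RSeT against primed cells and 234 falls in RSeT+DT against RSeT, and its overlap was not counted. Both comparisons share the RSeT libraries, which alone gave a covariance of -0.0121 to -0.00442 in 100 simulations, but the observed covariance was 0.000505, with Pearson's r of 0.00413 (simulated -0.552 to -0.283) and Spearman's rho of -0.0918 (simulated -0.469 to -0.326). These values meet neither bound set. They lay above all simulated values, so they show no opposite change from repeat to repeat beyond that of the shared libraries. They leave out the mean shift of each comparison, so they do not decide whether interspersed repeats as a whole ran against the change between cultures. RSeT has only 2 libraries and was not split to remove the sharing.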
